A study of Homo sapiens with 6 samples.

How the data were processed

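SW480 is an established cell line grown from a human colorectal adenocarcinoma. Per the labels' protocols, its cells were transiently transfected by a liposome method with a plasmid that expresses TUSC3 or with the same plasmid carrying no insert (empty vector, EV), and biotin-labelled cRNA made from total RNA was hybridised to Affymetrix arrays. There were 3 arrays per group and 6 in all, and each sample's group came from its label. The labels number the replicates 1 to 3 in both groups. They do not say whether the replicates were grown or transfected on separate days, so the p-values measure only the spread between these samples, which may be technical.

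Per the submitters' processing notes, the arrays were processed with RMA, which corrects background, normalizes the arrays to a common distribution and summarises the probes of each probe set. The version of RMA, the array model and the definition of the probe sets are not given in the sources used here. The deposited values were log2 expression levels, 1 per probe set and array, with a median of 5.50 and a maximum of 14.06 on every array. The sorted values of the EV arrays and of TUSC3 replicates 2 and 3 were identical, and those of TUSC3 replicate 1 differed from them by at most 0.00179. Values made equal in this way cannot show a shift of most genes in 1 direction. TUSC3 replicate 1 held 22765 distinct values against 9648 on each other array, so its values had been rounded differently. No detection call was used here, so a low level was not told apart from background, and the number of arrays limits the precision.

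The table held 25088 probe sets. The platform annotation gave exactly 1 gene symbol for 23752 of them and several symbols for 0, and 1336 are unnamed here. No 2 probe sets shared a symbol, so each of the 23752 genes was measured by 1 probe set. The unnamed probe sets entered the test over all probe sets and were not named. The values were tested as deposited, without further normalization and without a filter on dim probe sets.

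Differences, TUSC3 minus EV, were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend or robust options, two-sided), once over all probe sets and once over the genes. P-values were adjusted by the Benjamini-Hochberg method and a threshold of 0.05 was used. Intervals are 95% confidence intervals from the moderated fit. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over 41 lists that had at least 5 measured members. The lists held 1081 genes, of which 1004 were measured, and TUSC3 was in none of them. An exact two-sided permutation test of 3 against 3 arrays cannot give a p below 0.1.

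The groups, tests, gene lists, alternatives and the rule for naming genes were set before the data were examined. The rule took TUSC3, then in each direction up to 12 genes past the threshold with non-overlapping groups by size of difference. Where fewer than 12 passed, it took all that passed and then the genes with the smallest unadjusted p up to 8 per direction, given as not past the threshold. It took the 4 members with the smallest p from each list past the threshold, at most 2 from each other list, and MAGT1 always. Genes named outside this rule are marked as chosen after their values were seen.

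Each result was recomputed with the values quantile-normalized again, with the arrays shifted to the same median, without the dimmest 30% of probe sets, with a trended and robust variance prior (for the lists trended only, since camera takes no robust option), with array weights, with the replicate number as a block, and without each array in turn. The gene count was also taken with a minimum change of 1.5-fold, and the lists were also tested with an estimated correlation and with ranks. Averaging the probe sets of a gene was not run, because each gene had 1 probe set.

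The procedure was tested on simulated data built for the comparison of TUSC3 with EV, with the real mean and spread of each of the 23752 genes and 200 changed genes. It recovered 56% of 50 genes changed 1.5-fold, 78% of those changed 2-fold, 96% of those changed 3-fold and 92% of those changed 4-fold, with 8 false calls. These shares hold with 200 genes changed at once. With fewer changed genes the adjustment asks for a smaller p, so the shares do not measure what was missed in the real data. In 20 simulated sets in which lists were shifted by 0.1 on the log2 scale with independent noise, camera recovered 100% of the shifted lists with 0 false calls at the preset correlation, and 71.2% with an estimated correlation. False calls were counted only among lists that share no gene with a shifted list. With independent noise the 0 false calls do not cover lists whose members vary together. In the real data the estimated correlation was 0.1545 for the hypoxia list and 0.0756 for the YAP list.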

Results

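Expression was measured on 6 Affymetrix arrays of SW480 colorectal cancer cells, 3 from cells transfected with the TUSC3 plasmid and 3 from cells transfected with the empty vector. TUSC3 encodes a subunit of the oligosaccharyltransferase, the complex of the endoplasmic reticulum that attaches N-glycans to newly made proteins, and has been studied as a candidate tumour suppressor. The comparison asked which transcripts differ when TUSC3 is added to these cells. All values are log2 RMA levels, and all differences are TUSC3 minus EV.

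TUSC3 transfection raised the TUSC3 signal by 8.60 on the log2 scale, and no other gene passed the threshold. As groups, hypoxia-inducible genes were slightly lower in the TUSC3 arrays, and YAP and TEAD targets, ribosome biogenesis genes and G2 and mitosis genes were slightly higher, with mean shifts between -0.13 and 0.10. The calls of these 4 lists were all lost with an estimated correlation (adjusted p = 0.613 with an estimated correlation for each). That setting recovered 71.2% of shifted lists in simulated sets with independent noise. A lost call is thus not by itself evidence that a shift is absent. No list of glycosylation genes, endoplasmic reticulum stress genes, WNT targets or epithelial and mesenchymal markers passed the threshold.

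The TUSC3 level was 13.11 ± 0.022 (SD, n = 3) in the TUSC3 arrays and 4.51 ± 0.16 (SD, n = 3) in the EV arrays. The arrays with the plasmid read 13.13, 13.11 and 13.09, and those with the empty vector 4.57, 4.33 and 4.63. The difference was 8.60 with an SE of 0.091 and a 95% interval of 8.39 to 8.82 (limma, adjusted p = 7.71e-08). As a ratio of array signals this is 389-fold with an interval of 335- to 451-fold, which covers the spread between arrays and not background in the EV arrays or saturation in the TUSC3 arrays, so it is not a ratio of transcript amounts. The exact permutation p was 0.1, the smallest that 3 against 3 arrays can give. Where in the transcript this probe set lies is not given in the sources used here, so message from the plasmid and from the cells' own gene was not told apart.

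**Figure D1:**
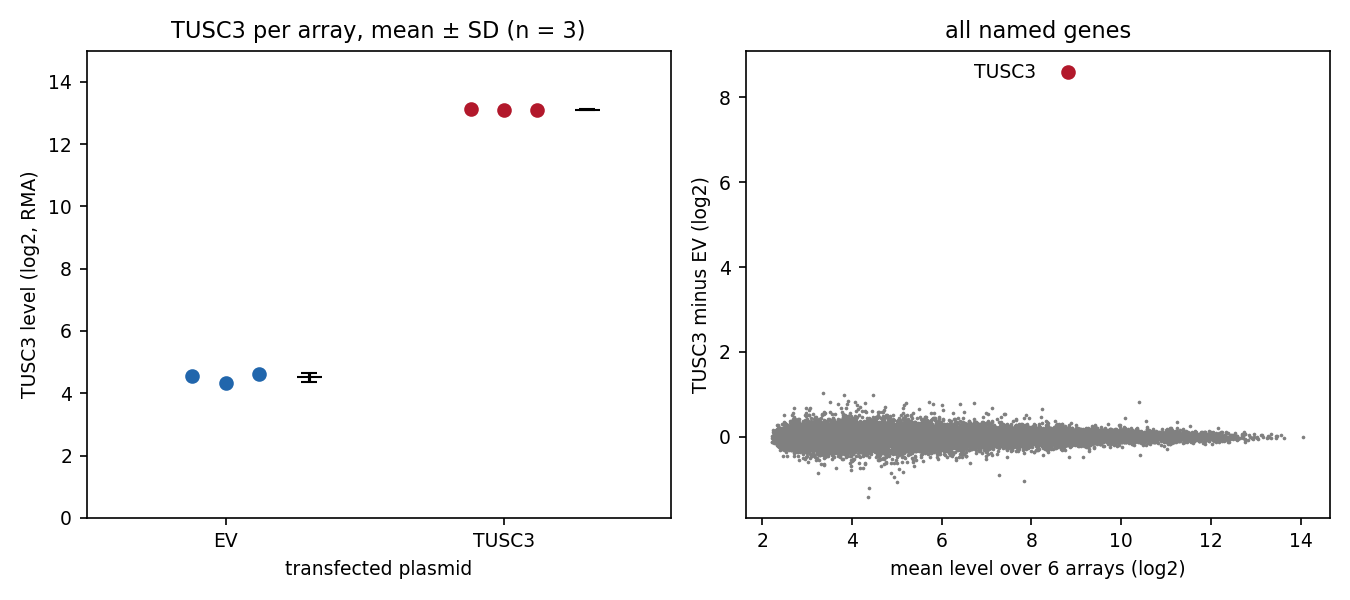
Left, the TUSC3 level (log2, RMA) on each of the 3 EV and 3 TUSC3 arrays as points, with the mean and SD of each group beside them. Right, the difference TUSC3 minus EV (log2) of each named gene against its mean level over the 6 arrays (log2), where TUSC3 stands at 8.60 and the other genes lie between -1.42 and 1.02.

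Of the 23752 genes, 1 was higher past the threshold, TUSC3, and 0 were lower (limma). The same count of 1 was found over all 25088 probe sets. At an unadjusted p under 0.05 there were 1593 genes, 809 higher and 784 lower, where 1188 would be expected from a uniform distribution. Among the 23751 genes other than TUSC3, the 95% interval excluded a change of 1.5-fold or more for 91.1% and a change of 2-fold or more for 99.1%. No detection call was used, so these intervals bound changes in array signal and not in transcript amount. The 3 TUSC3 arrays all lay above the 3 EV arrays for 1464 of these genes and all below for 1443, together 12.2%, where chance gives 10%.

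ORM1, which encodes the acute-phase plasma protein orosomucoid, had the lowest adjusted p after TUSC3, 0.117, with a difference of -0.75 from an EV mean of 4.02. SAA1, another acute-phase gene, was expressed at 9.86 ± 0.097 (SD, n = 3) in EV and differed by 0.45 (adjusted p = 0.630). SAA1 passed the threshold in 1 of 12 alternatives, the trended and robust variance prior (adjusted p = 0.0307, range 0.0307 to 0.838 over the alternatives). The other genes with the smallest p on the higher side were TEX46 (0.54), MIR3160-1 (0.69), CYP4F30P (0.53), RNASE2CP (0.60), HTR6 (0.45) and COL1A2-AS1 (0.37). On the lower side they were the homeobox gene DLX1 (-0.46), ADAM18 (-0.47), SEC14L6 (-0.51), MIR377 (-0.51), RTL8C (-0.47), ZC3H12D (-0.54) and the imprinted gene NNAT (-0.44). None of these passed the threshold.

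Another 5 genes, chosen after their values were seen, differed by more than 2-fold without passing the threshold. CYP21A2, the steroid 21-hydroxylase gene, differed by -1.42, LINC01376 by -1.21, PRAMEF7 by -1.08, SNORA2A by -1.05 and OR51A4 by 1.02. Their intervals were wide, -2.35 to -0.48 for CYP21A2 and -0.21 to 2.25 for OR51A4.

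Hypoxia and HIF targets, genes induced when oxygen is low, fell as a group. Of 24 measured members 19 were lower and 5 higher, the median difference was -0.062 and the mean -0.13 (camera, adjusted p = 0.00265; adjusted p = 0.613 with an estimated correlation). The members with the smallest p were PFKFB4, a regulator of glycolysis, at -0.44, NDRG1, a stress-responsive gene, at -0.44, EGLN3, a prolyl hydroxylase that marks HIF for degradation, at -0.90, and ANKRD37 at -0.26. The interval of EGLN3 ran from -1.51 to -0.29. No member passed the threshold over all genes, and 0 passed when adjusted over the list alone. Glycolysis genes, a separate list, did not pass (12 of 18 lower, adjusted p = 0.344), with ALDOC at -0.28 and PFKM at -0.18.

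YAP and TEAD targets, genes driven by the transcriptional arm of the Hippo pathway, rose as a group. Of 23 measured members 18 were higher, with a median difference of 0.093 and a mean of 0.10 (camera, adjusted p = 0.00369; adjusted p = 0.613 with an estimated correlation). F3, which encodes tissue factor, the initiator of coagulation, differed by 0.40 with an interval of 0.21 to 0.59. CCN1, a secreted matricellular protein gene, differed by 0.28, DLC1 by 0.23 and the transcription factor gene FOXF2 by 0.21. Over all genes 0 members passed, and adjusted over the list alone 1 did, F3.

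Ribosome biogenesis and MYC targets rose as a group and were higher in 22 of 27 measured members, with a mean difference of 0.063 (camera, adjusted p = 0.0197; adjusted p = 0.613 with an estimated correlation). GAR1, a component of the small nucleolar particles that guide pseudouridylation, differed by 0.25, RRP9 by 0.18, MRTO4 by 0.14 and the RNA polymerase subunit gene POLR1C by 0.14. G2 and mitosis genes also rose as a group and were higher in 29 of 38 members, with a mean difference of 0.056 (camera, adjusted p = 0.0345; adjusted p = 0.613 with an estimated correlation). PTTG1, which encodes securin, differed by 0.33, the cyclin-dependent kinase partner CKS2 by 0.25, the centromeric histone CENPA by 0.18 and CDC20, an activator of the anaphase-promoting complex, by 0.17. No member of either list passed over all genes, and 0 did when adjusted over the list alone. S-phase and DNA replication genes, higher in 26 of 35 members, did not pass (adjusted p = 0.114), with TYMS at 0.17 and RFC5 at 0.15. Replication-dependent histones did not pass (adjusted p = 0.282), with H3C10 at 0.35 and H2BC12 at 0.21. Cytosolic ribosomal protein genes did not pass (adjusted p = 0.396), with RPS16 at 0.17 and RPL34 at 0.18.

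**Figure D2:**
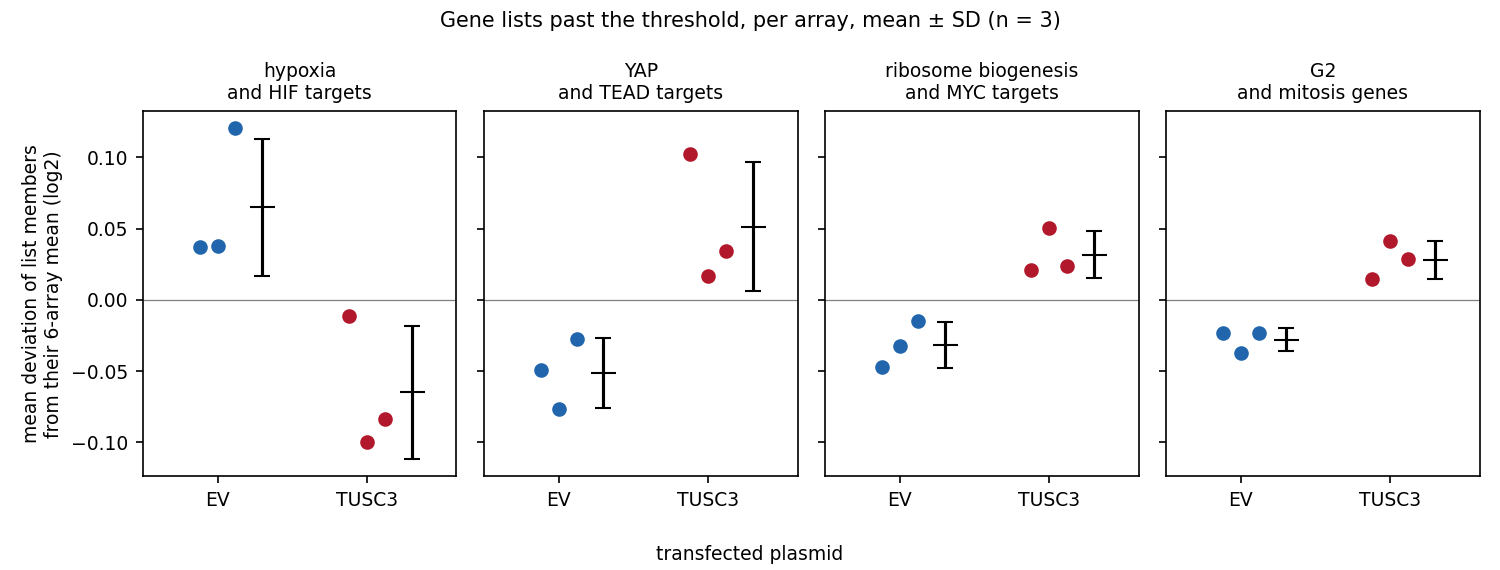
Mean deviation of the members of each list past the threshold from their mean over the 6 arrays (log2), 1 point per array for the 3 EV and 3 TUSC3 arrays, with the group mean and SD beside the points. In each of the 4 lists the TUSC3 arrays and the EV arrays do not overlap, for hypoxia and HIF targets with TUSC3 at -0.065 and EV at 0.065 on average.

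**Figure D3:**
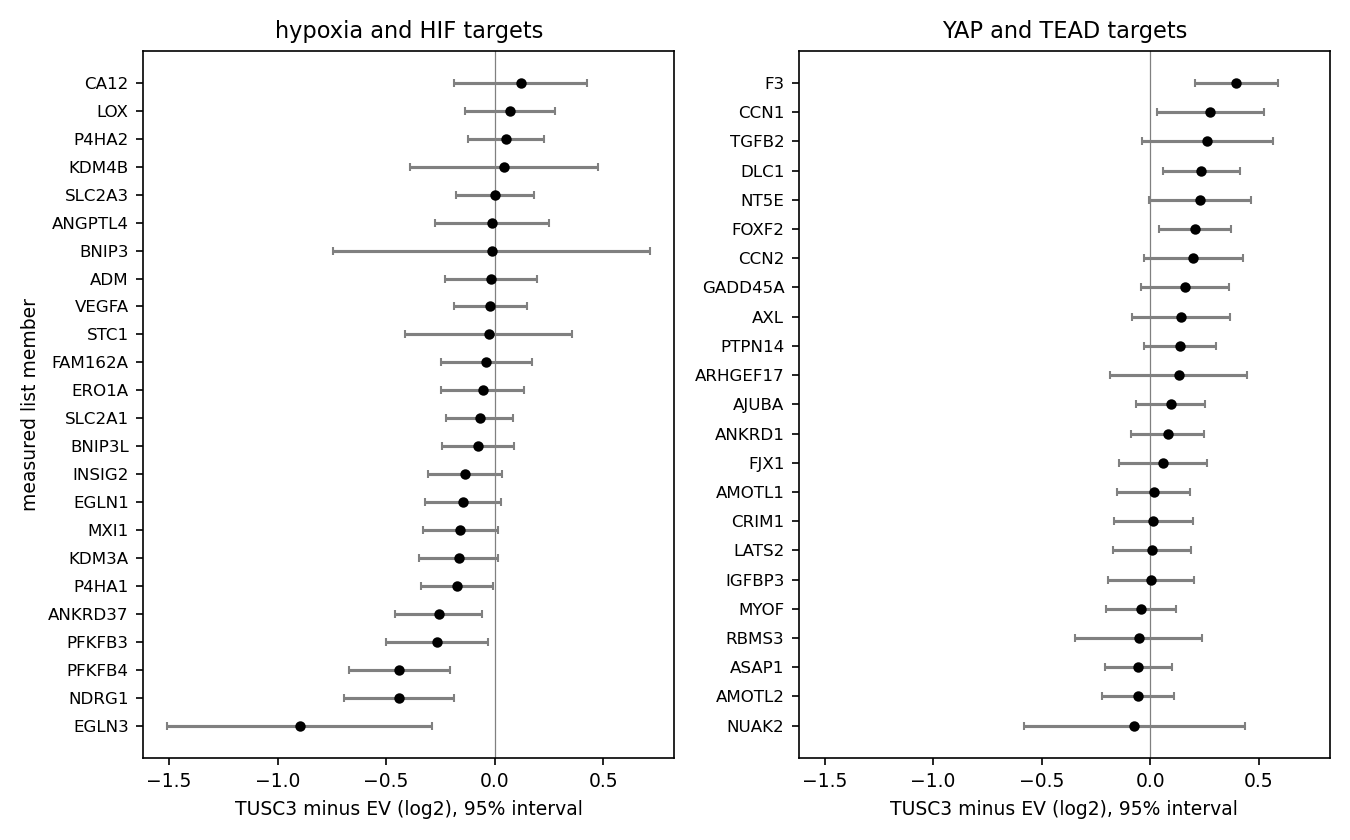
Difference TUSC3 minus EV (log2) of each measured member of the hypoxia and HIF targets (left, 24 genes) and of the YAP and TEAD targets (right, 23 genes), as points with 95% intervals. EGLN3, at -0.90, lies farthest below 0 on the left, and F3, at 0.40, farthest above 0 on the right.

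The arrays of the groups did not overlap in any of the 4 list means (exact permutation p = 0.1 for each, the smallest 3 against 3 arrays can give). Leaving out 1 array ended the YAP call without TUSC3 replicate 1 (adjusted p = 0.0900) or EV replicate 2 (0.0592), the ribosome biogenesis call without TUSC3 replicate 2 (0.158), EV replicate 1 (0.120) or EV replicate 2 (0.0592), and the G2 and mitosis call without TUSC3 replicate 2 (0.194), TUSC3 replicate 3 (0.0760), EV replicate 1 (0.0719) or EV replicate 2 (0.134). The hypoxia call held in all 6 leave-outs, with adjusted p up to 0.0470, and a trended variance prior gave 11 lists in place of 4, adding S-phase, NF-kB, FOXO, cholesterol synthesis, ERK, NRF2 and oxidative phosphorylation genes.

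The other subunits of the oligosaccharyltransferase did not pass as a list, with 8 of 11 higher and a mean difference of 0.038 (adjusted p = 0.396). MAGT1, the paralogue of TUSC3 that occupies the same place in the complex, had a level of 9.93 in EV and a difference of 0.03 with an interval of -0.13 to 0.19. OSTC differed by 0.16 and DAD1 by 0.10. Genes of dolichol-linked oligosaccharide synthesis, which build the glycan that the complex transfers, did not pass (adjusted p = 0.629), and NUS1, a subunit of the enzyme that makes the dolichol chain, differed by -0.41 and ALG10B by -0.33. N-glycan branching enzymes of the Golgi did not pass (18 of 26 lower, adjusted p = 0.282), with MAN1A1 at -0.27 and ST3GAL6 at -0.30. Magnesium transport genes, a list that includes MAGT1, were lower in 14 of 19 members and did not pass (adjusted p = 0.336), with CLDN19 at -0.26 and TRPM7 at -0.14.

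Genes that respond to misfolded protein in the endoplasmic reticulum did not pass. The ATF6 and XBP1 targets had a mean difference of -0.0016 over 25 genes (adjusted p = 0.853), with CRELD2 at 0.21 and EDEM1 at -0.12. ATF4 and integrated stress response targets had an adjusted p of 0.685, with the cystine transporter gene SLC7A11 at 0.24 and PPP1R15A at 0.17. The glycoprotein folding cycle and degradation list had an adjusted p of 0.956, with UBE2J1 at -0.18 and OS9 at -0.12, and its median and mean lay above 0 while camera gave the lower direction. Genes of disulfide formation did not pass (adjusted p = 0.571), with ERO1B at -0.15 and SELENOS at 0.11. Cytosolic heat shock genes had an adjusted p of 0.396, with HSPA4 at -0.09 and DNAJB4 at 0.10, and autophagy and lysosome genes one of 0.445, with ULK2 at -0.28 and GABARAPL1 at 0.40.

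NF-kB targets and inflammatory cytokines lay nearest to the threshold among the lists that missed it (19 of 28 higher, mean difference 0.093, adjusted p = 0.0610; adjusted p = 0.613 with an estimated correlation). TNFAIP3, a feedback inhibitor of NF-kB, differed by 0.42 and passed when adjusted over the list alone, the 1 member that did, and RELB differed by 0.29. FOXO targets, genes that AKT signalling represses, were lower in 17 of 24 members (adjusted p = 0.105), and KLHL24, at -0.33, was the 1 member that passed when adjusted over the list alone, with SESN3 at -0.25. In the other 38 lists, those beside YAP, NF-kB and FOXO targets, 0 members passed when adjusted over the list alone. ERK and serum immediate-early targets had an adjusted p of 0.128, with KLF4 at 0.28 and CCN1 again at 0.28. NRF2 targets had one of 0.149, with SLC7A11 at 0.24 and the metallothionein MT1F at 0.20. Interferon-stimulated genes did not pass (adjusted p = 0.495), with BST2 at -0.25 and IFIH1 at 0.22, nor did antigen presentation genes (adjusted p = 0.956), with PSMB10 at 0.30 and CD74 at -0.22. The mean of the antigen presentation list lay above 0 and its median and camera direction below.

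Lists tied to tumour identity and invasion did not pass. WNT and beta-catenin targets had an adjusted p of 0.573, with TNFRSF19 at -0.23 and NOTUM at -0.19. Mesenchymal markers had one of 0.797, with ITGA5 at -0.29 and MMP9 at 0.17, and epithelial junction and keratin genes one of 0.411, with the desmosomal cadherin DSG2 at -0.16 and the splicing regulator ESRP1 at -0.18. Integrins, laminins and adhesion glycoproteins had an adjusted p of 0.707, with ITGA5 at -0.29 and CEACAM6 at 0.36 from an EV level of 2.44. TGF-beta and SMAD targets likewise had 0.707, with LTBP2 at 0.19 and BMP4 at 0.20. Receptor tyrosine kinases and ligands had 0.608, with DDR1 at -0.24 and IGFBP4 at -0.13, and intestinal differentiation genes 0.797, with CEACAM6 at 0.36 and TFF3 at 0.16. Targets of p53 had 0.797, with TP53INP1 at -0.44 and GDF15 at -0.20, and their median lay above 0 while their mean and camera direction lay below. Apoptosis regulators had 0.445, with BAK1 at 0.34 and BMF at -0.40.

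Cholesterol synthesis genes were lower in 14 of 19 members and did not pass (adjusted p = 0.106), with INSIG1 at -0.14 and SQLE at -0.12. PPAR targets had an adjusted p of 0.195, with PLIN2 at -0.21 and HADHA at -0.12, and fatty acid synthesis genes one of 0.336, with FADS2 at -0.20 and ACSL1 at -0.15. Oxidative phosphorylation genes had 0.257, with NDUFS8 at 0.17 and COX8A at 0.15.

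Markers of other cell types did not move past the threshold with the groups. Leukocyte markers had an adjusted p of 0.445, with CD3D at 0.20 and LYZ at -0.20. Fibroblast markers had one of 0.956, with THY1 at -0.33 and S100A4 at 0.17, and endothelial markers one of 0.552, with KDR at -0.24 and VWF at 0.17. Neural crest, muscle and germ line genes had 0.608, with MLANA at 0.23 and DES at -0.17. Of the 41 lists, 10 had an unadjusted p under 0.05, 4 passed after adjustment, and 0 passed with an estimated correlation.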

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

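The alternatives were chosen before the data were examined. The TUSC3 difference stayed between 8.51 and 8.66 and past the threshold in all 12 alternatives run on it, the gene and probe set counts stayed at 1 in each leave-out, and no result turned direction while past the threshold. The trended and robust prior gave 2 probe sets and 2 genes, both higher, the added one SAA1 (adjusted p = 0.0307), and 11 lists, which included the 4 and added S-phase genes (adjusted p = 0.0108), NF-kB, FOXO and cholesterol synthesis genes (0.0185 each), ERK and NRF2 targets (0.0203 each) and oxidative phosphorylation genes (0.0436); the cause was not tested. With an estimated correlation 0 lists passed, and the hypoxia, YAP, ribosome biogenesis and G2 lists each had an adjusted p = 0.613. Behind this shared value their unadjusted camera p were 0.106, 0.0643, 0.02325 and 0.0528, in that order. Their estimated correlations were 0.1545, 0.0756, -0.0177 and 0.0159, against the preset 0.01. A correlation above the preset cannot account for the lost ribosome biogenesis call, because its estimate lay below the preset. In the simulated sets with independent noise this setting also lost calls, with 71.2% of shifted lists recovered against 100% at the preset. A call lost with an estimated correlation is therefore not by itself a sign that members vary together. What caused the loss was not tested further. Without 1 array, 2 to 5 lists passed, with adjusted p from 0.00332 to 0.0900 for YAP and TEAD targets, 0.0298 to 0.158 for ribosome biogenesis and MYC targets, 0.0391 to 0.194 for G2 and mitosis genes and 0.000325 to 0.0470 for hypoxia and HIF targets; these fits hold fewer arrays. Replicates with the same number did not deviate together (correlations -0.014, 0.043 and -0.011, none over 0.1). Both replicates 2 correlated best with each other. So did TUSC3 replicate 1 with EV replicate 3, and TUSC3 replicate 3 with EV replicate 1. A pairing other than by the same number was not tested. With the replicate block 1 gene and 5 lists passed, the added one NF-kB targets (adjusted p = 0.0499). NF-kB targets also passed without the dimmest 30% (adjusted p = 0.0347, range 0.0185 to 0.613 over 14 alternatives). Among the single lists and genes, 527 list values and 1211 gene values kept their direction and side of the threshold, 13 list values and 1 gene value newly passed, 13 list values lost the call, and 21 list values and 1 gene value, of MAGT1, changed sign without passing. Averaging the probe sets of a gene, and each TUSC3 probe set by itself, were not run, because each gene had 1. The files used here give no signal over background, so how far low levels are limited by it was not measured.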

Other observations

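The tests of the array that carries a shift, of cell density, of dim probe sets, of a mislabelled array and of the splits for genes and lists were chosen only after the result was seen.

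The real grouping gave 1 gene and 4 lists against at most 0 genes and 1 list in the other 9 splits. Of those, 3 called a list and 1 (TUSC3 replicate 1 with EV replicates 1 and 3) called the hypoxia list itself. The 10 splits are too few for a share under 0.05. The 1 gene was TUSC3, and a split that mixes the groups puts its difference into the spread within each part. TUSC3 could therefore not be called in the other splits, and the gene counts decide nothing about its call. Leaving out any 1 array kept at least 0.787 of the mean shift for hypoxia, 0.749 for YAP, 0.851 for ribosome biogenesis and 0.884 for G2 and mitosis genes, which argues against 1 array carrying the shift, and among 10000 random lists matched on size and level the means lay at percentiles 0.01, 99.5, 99.8 and 99.4, which argues against a trend with intensity. A denser EV culture could raise hypoxia genes and lower YAP targets, but the array with the highest hypoxia score had the lowest YAP score in 0 of the 2 groups and the highest YAP score in both (TUSC3 replicate 1 at -0.012 and 0.10, EV replicate 3 at 0.12 and -0.028), opposite to what density would give. No count over 2 groups of 3 arrays could decide this test, so cell density cannot be told apart from an effect of TUSC3. That TUSC3 itself shifts these lists stays an untested hypothesis, and all 4 calls were lost with an estimated correlation (adjusted p = 0.613 with an estimated correlation). That setting also lost calls of lists that were shifted in simulated data.

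More genes than a uniform distribution gives, 1593, had an unadjusted p under 0.05, against at most 1434 in the other 9 splits, and 10 splits are too few for a share under 0.05. Without the differently rounded TUSC3 replicate 1 the share was 5.87%, the lowest of the 6 leave-outs (the next 5.89% without TUSC3 replicate 2, the highest 7.35%) and still above 5%, which argues against its rounding as the whole cause. The genes brighter than the median gene gave 5.79% in the real split and at most 3.68% in the others, and the dimmer genes 7.62%, inside the range of the others (6.47% to 8.39%). A share above 5% was thus not confined to the dimmer genes. The 10 splits are again too few for a share under 0.05, so noise of dim probe sets was not excluded. Small differences due to TUSC3, or to how the cultures were handled, stay open.

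TUSC3 replicate 3 stood nearer to the EV arrays than the other TUSC3 arrays did on the first principal component of all genes without TUSC3 (23.3% of the variance), at -0.45 against 18.64 and 11.08, with EV at -10.62, -7.18 and -11.46. Its TUSC3 level was 8.46 above that of the highest EV array, which argues against a mislabelled array. Without it, NF-kB targets and ERK targets passed (adjusted p = 0.0193 for both, over alternatives 0.0185 to 0.613 and 0.0188 to 0.666) and G2 and mitosis genes did not (adjusted p = 0.0760, over alternatives 0.000742 to 0.613). These gains were not particular to this array, since NF-kB targets also passed without EV replicate 2 (adjusted p = 0.0316) and ERK targets without EV replicate 1 (adjusted p = 0.0188). What set TUSC3 replicate 3 apart was not tested further.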
